A study of Mus musculus with 6 samples.

How the data were processed

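Small RNA was profiled in the hearts of 6 wild-type male C57BL/6J mice aged 18 weeks, with 1 library per sample, named here heart 1 to heart 6 after the replicate number in the labels. C57BL/6J is the common inbred laboratory strain of the mouse. The labels name the tissue as the whole heart, while their extraction protocol describes frozen tips of the ventricles, so the part of the heart that was sampled is uncertain. Per the labels' protocols, total RNA was taken up in Trizol, and adapters were ligated to both ends of the small RNA with a TruSeq kit before reverse transcription, a short PCR and size selection. Such ligation favours some RNA ends over others, so a ratio between different miRNAs is a ratio of reads, not of molecules, while the same miRNA can be compared between hearts. The reads carried no molecular identifiers, so every counting interval below covers counting error only.

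The deposited files hold whole-number read counts per mature miRNA arm and locus, not normalized, and are used as the authors deposited them. Per the file headers, each row gives a name, a location and a count, and the 6 files list the same 1102 entries. Each entry had at least 1 read in at least 1 library. Per the submitters' processing notes, the genome build was GRCm38, and edgeR and DESeq are named without a role or version. The aligner, the counting program and the treatment of reads that match several loci are not given in the sources used here. All positions below are those of the files, on GRCm38, counted from 1, and were checked against the hairpin sequences of a GRCm38 annotation. That annotation also gave the genes that overlap each hairpin, where exonic means overlap with an exon of some annotated transcript.

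Of the entries, 1026 were sense and 76 antisense to the hairpin that the file names. An antisense entry was assigned to the hairpin annotated on the opposite strand at the same position where there was one, which resolved 38 entries. They carried 13.2% ± 1.37 (SD, n = 6) of the counts, mostly miR-486-5p. The other 38 antisense entries held at most 0.000706% of a library and were left out of library totals and tests. Entries of the same mature name at different loci were summed, since near-identical copies can share reads, which gave 975 mature miRNAs, 68 of them from more than 1 entry. Some summed entries, such as those of let-7a-3p and miR-125b-3p, differ in sequence between loci and were summed by name only. The library totals ran from 3966169 to 6007322 counts, so 10 reads correspond to between 1.66 and 2.52 CPM, and the limit that a count of 0 allows (3 counts) to between 0.499 and 0.756 CPM.

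CPM is the count scaled to a library of 1000000 counts and was computed on the total of each library. The samples form 1 group, so no contrast between groups was made. Named miRNAs follow a rule set before the data were examined. It takes the 20 with the highest mean CPM, the members of 14 fixed lists, and the 10 most and 5 least variable miRNAs with a mean of at least 100 reads. It also takes the 5 hairpins with the largest excess of each arm, called list members, and 18 preset pairs. The lists are cardiac and skeletal muscle, endothelial, smooth muscle, fibroblast and mesenchymal, erythroid, leukocyte, muscle and erythroid, other tissues, the let-7, miR-30, miR-29 and miR-15/16 families, miR-17-92 and paralogs, and the Dlk1-Dio3 locus.

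The arms of each hairpin and the preset pairs were compared with the edgeR quasi-likelihood test, with the library as a block and Benjamini-Hochberg adjustment. Hairpins that share a mature name were summed and count as 1 hairpin in these tests. A hairpin was tested if both arms had an entry and a mean of at least 10 reads together. It was called at an adjusted p under 0.05 and at least a 2-fold ratio. The spread between hearts is the biological coefficient of variation (BCV) that edgeR estimated after TMM scaling. The BCV of a single miRNA is a tagwise estimate, which edgeR draws toward that of miRNAs of similar abundance. Each miRNA was also tested against counting noise by a chi-square test of its 6 counts. Co-variation within genomic clusters is the median Pearson r over pairs from different hairpins of a cluster, on log2 CPM after TMM scaling with a prior count of 1. It was tested with 100000 permutations of the cluster membership, one-sided. Co-variation of the 6 cell-type lists used an exact permutation test, two-sided, over 15 pairs.

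The p-values of the arms, preset pairs and lists concern only the spread between these samples. Those of the arms use a spread that edgeR largely pooled over the hairpins, not that of each hairpin alone. For miR-30d the SE of the log2 ratio was 0.122, while its SD over the 6 libraries was 0.0645. The cluster p-value comes from permuting miRNAs, not hearts, and the chi-square p-values compare the 6 counts with counting noise. No pair of libraries agreed within sampling noise, so none was a file deposited again. This check would not find libraries prepared separately from 1 sample, and the 6 were treated as separate samples after the labels. The alternatives were DESeq2 and limma as tests, DESeq2 size factors and library totals as scalings, other count minimums, Spearman correlation, and leaving out each heart in turn. Alternatives chosen after the data were examined were clusters taken from coordinates with at most 10 kb between hairpins, clusters without the Dlk1-Dio3 locus, and results without hearts 4 and 5.

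The scripts were tested on simulated data. For the arm ratio, with 211 hairpins of which 100 were changed, 79.4% of 1.5-fold changes and 100% of both 2-fold and 4-fold changes reached the adjusted threshold, and 3.6% of unchanged hairpins did. For the preset pairs, 93% of 1.5-fold differences were recovered over 50 simulations of 18 pairs, and 4.33% of equal pairs were called. All simulated arms and pairs had the same BCV, the simulated arms differed at most 4-fold, and low means of the pairs were raised. These rates therefore do not cover hairpins or pairs of unequal spread, larger ratios, or arms and members with a few reads over all libraries. For the spread, a simulated BCV of 15% was recovered as 15.2% over 346 miRNAs. For the clusters, over 207 miRNAs, 100% of 40 simulations with a cluster effect as large as the noise were called and 0% of 40 without one. For the lists, 5% of 40 simulations of unrelated lists gave any call. The versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.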

Results

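The series describes the miRNA profile of the normal adult mouse heart. MicroRNAs (miRNAs) are small regulatory RNAs cut from the 5p or 3p arm of a hairpin precursor. Hearts of 6 wild-type male C57BL/6J mice aged 18 weeks were profiled, 1 library each. The libraries of hearts 1 to 6 held 4761602, 4966707, 4226580, 3966169, 6007322 and 5602776 counts, so the deepest had 1.51 times the counts of the shallowest. Unless stated otherwise, values are means ± SD over these 6 hearts.

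A small number of miRNAs made up most of the profile. miR-22-3p, abundant in striated muscle, held 15.1% ± 1.11 of the counts, and miR-486-5p, an miRNA of muscle and red cells encoded in the ankyrin gene Ank1, held 14.2% ± 2.29. The muscle miRNA miR-133a-3p held 8.90% ± 0.441, the smooth muscle miRNA miR-143-3p 8.90% ± 1.66, and miR-126a-5p, from the endothelial gene Egfl7, 7.76% ± 0.434. miR-30a-5p followed with 5.76% ± 0.329, miR-26a-5p with 3.96% ± 0.541, miR-27b-3p with 3.60% ± 0.196, and miR-378a-3p, from an intron of Ppargc1b, with 3.07% ± 0.360. miR-10a-5p was the tenth at 2.20% ± 0.236. The next 10, from miR-30d-5p (2.09% ± 0.198) to let-7f-5p (0.772% ± 0.0721), included miR-30e-5p, miR-10b-5p, miR-191-5p, miR-16-5p, miR-126a-3p, miR-148a-3p, miR-30c-5p and miR-181a-5p. The top 10 together held 73.4% ± 1.12 of the counts, the top 20 held 87.5% ± 0.616 and the top 100 held 99.1% ± 0.0491. Of 975 mature miRNAs with a read, 346 had a mean of at least 10 reads. This number depends on the minimum, with 594 at a mean of at least 1 read and 207 at 100.

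**Figure D1:**
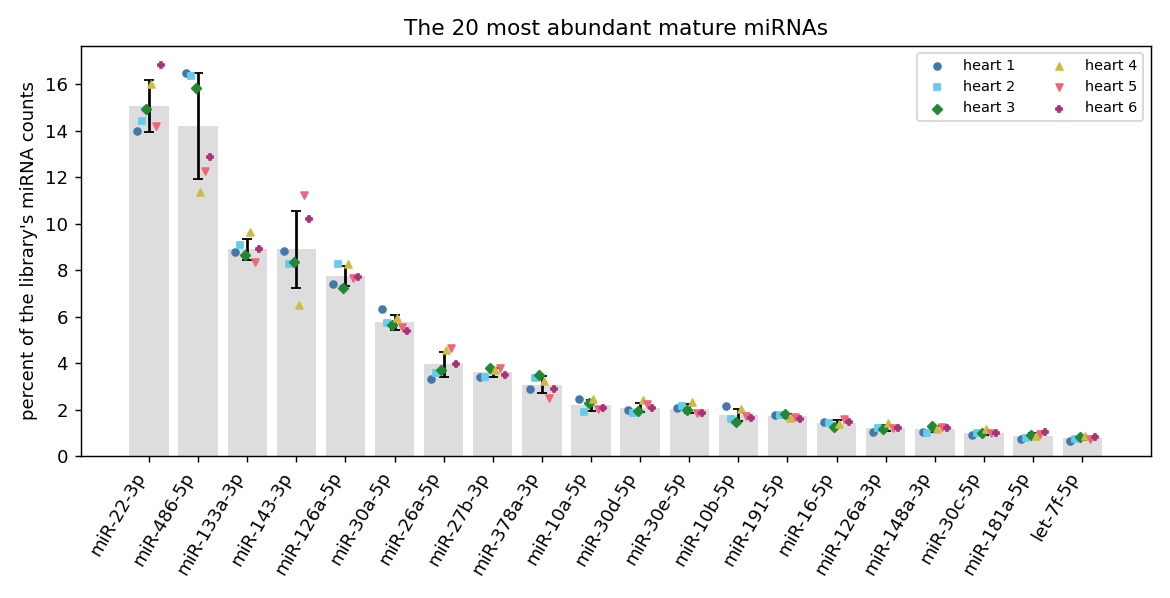
Percent of each library's miRNA counts (vertical axis) for the 20 miRNAs with the highest mean CPM, with grey bars for the mean, error bars for the SD over 6 hearts and a point for each heart. miR-486-5p and miR-143-3p had the widest SDs, 2.29% and 1.66% of the counts, while miR-133a-3p, at a similar level to miR-143-3p, had 0.441%.

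The loci of the leading miRNAs lie on several chromosomes. miR-22-3p (AAGCTGCCAGTTGAAGAACTGT) lies on chromosome 11 from 75463772 to 75463793, in exons of Mir22hg and Tlcd2. miR-133a-3p (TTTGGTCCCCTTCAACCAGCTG) comes from 2 loci, and most of its reads were booked on the copy on chromosome 2 from 180398437 to 180398458, outside annotated genes. miR-126a-5p (CATTATTACTTTTGGTACGCG) lies on chromosome 2 from 26591365 to 26591385, in sequence that is exonic in a transcript of Egfl7. miR-143-3p (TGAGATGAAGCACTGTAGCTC) lies on chromosome 18 from 61649199 to 61649219, outside annotated genes. The 5p and 3p strands of miR-486 are near complements of each other on chromosome 8 from 23142629 to 23142649, where hairpins are annotated on both strands, so its reads were summed over both.

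The muscle, endothelial and smooth muscle lists held similar shares of the counts. Each list was mostly 1 miRNA, so these shares do not measure how much of each cell type was present. The muscle list leaves out miR-22-3p and miR-486-5p, which are described above as found in muscle and held larger shares. Its share also depends on miR-1a-3p, whose few reads next to miR-133a-3p are unexplained. If reads of miR-1a-3p were lost, which stays open below, this share is too low and the similarity of the lists would not hold. The cardiac and skeletal muscle list held 9.94% ± 0.463 of the counts, and miR-133a-3p made up 89.5% of it. miR-1a-3p, transcribed from the same loci as miR-133a-3p, stood at 7587 ± 1001 CPM, miR-208a-3p from an intron of the alpha myosin gene Myh6 at 1227 ± 270 CPM, and miR-499-5p from the myosin gene Myh7b at 1126 ± 89.8 CPM. miR-133b-3p (352 ± 65.5 CPM) and miR-208b-3p from the beta myosin gene Myh7 (118 ± 46.7 CPM) were the lowest of the list. The endothelial list held 9.004% ± 0.538, of which 86.2% was miR-126a-5p, with miR-221-3p at 233 ± 23.9 CPM and miR-222-3p at 93.4 ± 14.4 CPM. The smooth muscle list held 9.03% ± 1.67, of which 98.5% was miR-143-3p, and miR-145a-5p from the same cluster stood at 745 ± 157 CPM.

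The fibroblast and mesenchymal list held 2.17% ± 0.291 of the counts, led by miR-10b-5p at 17733 ± 2628 CPM and miR-199a-3p at 3121 ± 889 CPM, while miR-214-3p stood at 92.6 ± 13.7 CPM. The erythroid list held 0.395% ± 0.143 and ranged 2.6-fold between hearts, from 0.226% in heart 4 to 0.588% in heart 1. It was led by miR-451a at 3476 ± 1299 CPM, with miR-144-3p at 336 ± 118 CPM. The leukocyte list held 0.352% ± 0.0312, with miR-142a-5p at 1251 ± 278 CPM, the lymphocyte miRNA miR-150-5p at 960 ± 156 CPM, miR-146a-5p at 947 ± 151 CPM and the myeloid miRNA miR-223-3p at 143.5 ± 24.1 CPM. The list shared by muscle and erythroid cells, miR-486-5p and miR-486-3p, held 14.2% ± 2.29.

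miRNAs of other tissues held 0.385% ± 0.0564 of the counts, and 86.7% of that was miR-192-5p, known from gut and kidney, at 3338 ± 508 CPM. miR-194-5p (173 ± 12.4 CPM), miR-215-5p (99.8 ± 26.0 CPM), the epithelial miR-203-3p (78.4 ± 9.68 CPM) and miR-141-3p (37.4 ± 6.04 CPM), the liver miRNA miR-122-5p (44.3 ± 26.8 CPM) and the neural miR-9-5p (21.99 ± 2.38 CPM) followed. Of 27 members 13 had a mean of at least 10 reads. The skeletal muscle miRNA miR-206-3p had 1 read over the 6 libraries, or 0.0339 CPM (exact Poisson 95% interval 0.000857 to 0.189). Reads of some rare members lay mostly in heart 4, which held 13.4% of all counts. The neural miR-124-3p had 19 of its 25 reads there, and the exocrine pancreas miRNAs miR-216a-5p, miR-216b-5p and miR-217-5p had 10 of 10, 5 of 6 and 8 of 11. The other rare members together had 12 of 84 reads in heart 4, near its share of all counts. Among these, the neural miR-9-3p had 6 of 42. Pooled over the other 5 hearts, miR-124-3p stood at 0.235 CPM and miR-217-5p at 0.117 CPM, against 4.79 and 2.02 CPM in heart 4. miR-375-3p of the endocrine pancreas stood at 23.4 CPM in heart 4 and between 0.420 and 2.16 CPM in the other 5 hearts.

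Among families, miR-30 held 11.2% ± 0.566 of the counts, let-7 1.94% ± 0.1435, miR-15/16 1.74% ± 0.113 and miR-29 0.760% ± 0.0808. miR-30a-5p made up 51.7% of its family, let-7f-5p 39.8%, miR-16-5p 82.4% and miR-29a-3p 79.9%. miR-17-92 and paralogs held 0.467% ± 0.0290, led by miR-92a-3p (2537 ± 287 CPM) and miR-25-3p (1223 ± 60.8 CPM). The Dlk1-Dio3 imprinted locus on chromosome 12 held 0.203% ± 0.0519, with 23 of 70 listed members at a mean of at least 10 reads. miR-127-3p made up 69.5% of it at 1413 ± 376.1 CPM, followed by miR-411-5p at 227 ± 52.1 CPM and miR-541-5p at 96.6 ± 20.3 CPM. Heart 5 had 0.305% in this locus, against 0.168% to 0.202% in the other 5.

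**Figure D2:**
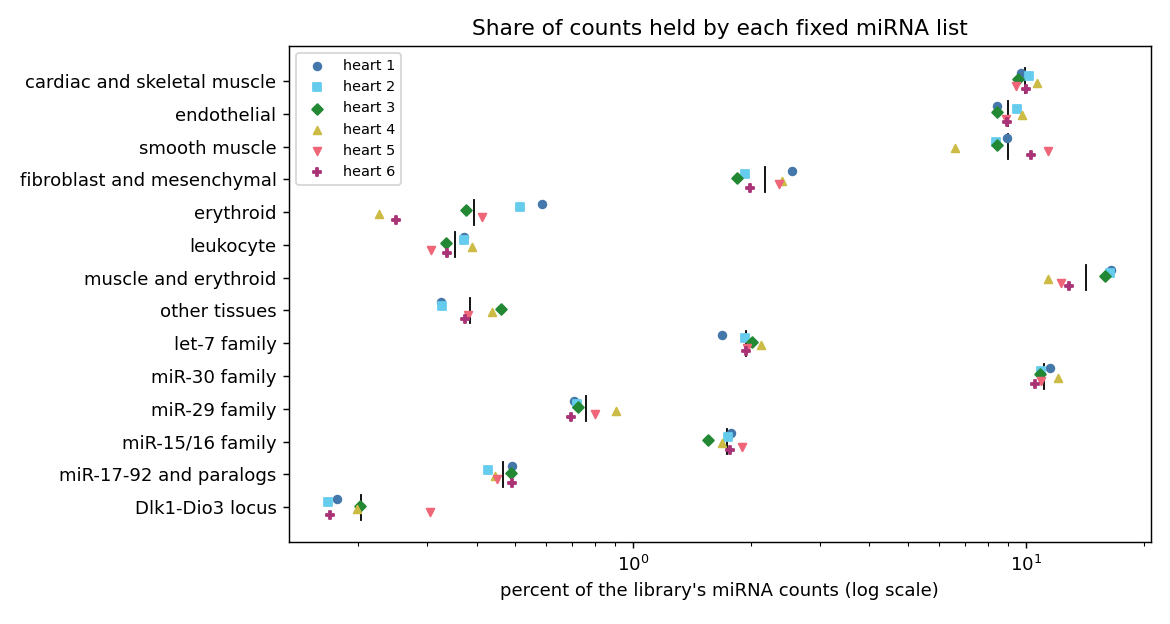
Percent of each library's miRNA counts (horizontal log axis) held by each of the 14 fixed lists, with a point for each heart and a black line for the mean of 6. The erythroid list spread most, from 0.226% to 0.588%, and heart 5 stood apart in the Dlk1-Dio3 locus at 0.305%.

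Most of the hairpins tested yielded reads mainly from 1 arm. Hairpins of one name, such as those of miR-26a, were summed and count as 1 here. Of 211 hairpins tested, 102 gave more 5p and 86 more 3p reads, and the other 23 were not called (edgeR quasi-likelihood test, largest adjusted p of a call 0.00687, n = 6). The median ratio of the called hairpins was 39.8-fold. The largest excess of the 5p arm was found for miR-26a, with 10028 reads of 5p per read of 3p over the 6 libraries (exact binomial 95% interval 8367 to 12125). It was followed by miR-149 (ratio 9113, 3118 to 44192, with 3 reads of the 3p arm), miR-10b (6684, 5356 to 8456), miR-146a (5616, 2406 to 17296) and miR-192 (3907, 2646 to 6037). The largest excess of the 3p arm was found for miR-23a (ratio 11802, 4609 to 43318, with 4 reads of the 5p arm) and miR-23b (6241, 3029 to 15525), then miR-143 (4969, 4568 to 5416), miR-130a (2878, 1397 to 7159) and miR-103 (2636, 1279 to 6558). These intervals show that the counts settle only part of the order among them. miR-26a (8367 to 12125) lies above miR-192 (2646 to 6037). The intervals of miR-149, miR-146a and miR-23a overlap those of all others named for the same arm. The 3p arms of miR-23a and miR-23b share their first 18 bases, as do miR-103-3p and miR-107-3p. How their reads were divided could also move these 3p ratios.

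Listed miRNAs followed both patterns. The muscle hairpin miR-133a gave 0.319% ± 0.0214 of its reads from the 5p arm, and miR-1a gave 0.0720% ± 0.0302. miR-208a gave 6.01% ± 0.838 from the 5p arm and miR-499 99.2% ± 0.169. The endothelial miR-126a gave 86.5% ± 0.869 of its reads from the 5p arm, in contrast to miR-30a with 98.2% ± 0.266 and miR-16 with 99.9% ± 0.0112. On the fibroblast and mesenchymal list, miR-199a gave 14.6% ± 1.59 and miR-214 21.9% ± 2.80 from the 5p arm, in contrast to miR-10b, named above for its excess of 5p. miR-199a-3p and miR-199b-3p have the same sequence (ACAGTAGTCTGCACATTGGTTA), so their reads cannot be told apart and the arm shares of both hairpins are uncertain. miR-144 gave 29.2% ± 4.13 and miR-106b 70.0% ± 4.18. let-7d (1.29-fold more 5p, adjusted p = 0.00012, higher in 6 of 6 hearts) and miR-145a (1.38-fold more 5p, adjusted p = 1.72e-06, higher in 6 of 6) passed the p threshold with ratios under 2-fold. Their log2 ratios were 0.37 ± 0.21 and 0.46 ± 0.18 (SD), and these p-values rest on a spread largely pooled over hairpins. The sequence of each arm affects how well adapters ligate, so these are ratios of reads.

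miRNAs that share a transcript or a family differed widely in reads. miR-1a-3p was 11.8-fold lower than miR-133a-3p (log2 ratio -3.56 ± 0.09, SE, n = 6, adjusted p = 1.43e-09), in each of 6 hearts. Among the myosin miRNAs, miR-208a-3p was 10.9-fold above miR-208b-3p (log2 ratio 3.45 ± 0.29, adjusted p = 5.34e-06), and the ratio of their counts ran from 4.65 in heart 5 to 22.6 in heart 2. miR-499-5p was 10.2-fold above miR-208b-3p, and did not differ from miR-208a-3p beyond the spread (log2 ratio -0.10 ± 0.09, adjusted p = 0.309, higher in 2 of 6). miR-133a-3p was 256-fold above miR-133b-3p, whose neighbour miR-206-3p had 1 read in all.

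Partners of one cluster differed likewise. miR-143-3p was 120-fold above miR-145a-5p, miR-27b-3p 24.5-fold above miR-23b-3p, miR-451a 10.2-fold above miR-144-3p, miR-16-5p 132.2-fold above miR-15b-5p, and miR-199a-5p 5.61-fold above miR-214-3p. The counts of miR-16-5p and miR-199a-5p include another locus outside the cluster, and 92.9% of miR-16-5p and 56.7% of miR-199a-5p reads were booked on the copy in it. The partners miR-195a-5p and miR-497a-5p (3.24-fold) and miR-221-3p and miR-222-3p (2.51-fold) were closer. miR-29a-3p was 32.2-fold above miR-29b-3p, and miR-27b-3p 10.97-fold above miR-27a-3p, while miR-23a-3p and miR-23b-3p differed 1.08-fold (log2 ratio 0.12 ± 0.06, adjusted p = 0.0808, higher in 6 of 6 hearts). That last pair was called with DESeq2 (adjusted p = 0.00426), with adjusted p between 0.00426 and 0.197 over its alternatives. The pairs miR-133a-3p and miR-133b-3p, miR-23a-3p and miR-23b-3p, and miR-27a-3p and miR-27b-3p share their first 18 bases, so the counting could have divided their reads. In all, 16 of 18 pairs passed an adjusted p of 0.05 with the edgeR quasi-likelihood test.

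The 6 libraries, from hearts of one strain, sex and age, differed beyond counting noise in most miRNAs. With 1 library per heart, this spread includes library preparation as well as the hearts themselves. The common BCV was 18.9%, and 242 of 346 miRNAs varied more than counting allows (chi-square test, adjusted p under 0.05), while 104 did not. Of the 207 with a mean of at least 100 reads, 184 did and 23 did not. Many of the 104 therefore had few reads, where the test finds less, and need not be constant. Without hearts 4 and 5, an alternative chosen after the data were examined, the BCV was 14.9% and 190 of 338 miRNAs varied. The least variable of the abundant miRNAs by BCV were miR-27b-3p (BCV 11.1%), miR-30d-5p (11.3%), miR-133a-3p (11.4%), miR-30c-5p (11.4%) and miR-126a-5p (11.5%). These BCVs are drawn toward those of miRNAs of similar abundance and overstate the measured spread. The plain CVs of their scaled CPM (SD over mean) were 4.13%, 5.12%, 5.96%, 5.22% and 6.61% in that order. By plain CV they were not the 5 least variable. The lowest CV was 4.57% among let-7 members and 4.70% among miR-15/16 members, below each of the 5 except miR-27b-3p. List medians of the BCV among members with a mean of at least 100 reads were 11.8% for miR-30, 13.0% for let-7, 13.1% for endothelial, 16.5% for cardiac and skeletal muscle, 19.5% for fibroblast and mesenchymal, and 31.9% for erythroid miRNAs. The medians for miR-30, let-7 and endothelial miRNAs lie above the largest CV of a member (8.30%, 10.4% and 10.3%), so they overstate the spread of those lists.

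The 10 most variable miRNAs, given in CPM after TMM scaling, differed in which hearts stood out. miR-182-5p, known from sensory and epithelial cells, had a BCV of 75.3%, with 190 CPM in heart 4 and 25.6 to 51.1 in the others, and 22.8% without heart 4. The cartilage miRNAs miR-140-3p (BCV 41.0%) and miR-140-5p (40.5%), on chromosome 8 in Wwp2, had 1735 and 264 CPM in heart 5, and their BCV without heart 5 was 13.7% and 17.7%. miR-122-5p (BCV 65.6%) ranged 7.57-fold, lowest in heart 1 at 9.31 CPM, and miR-3057-5p (46.6%), in an exon of Apba3, 5.21-fold, lowest in heart 1 at 8.23 CPM. Without heart 1 these were 42.6% and 24.9%. miR-21a-3p (37.4%) was highest in heart 1 at 75.6 CPM and had a BCV of 22.2% without it. The erythroid miR-451a (38.7%) ranged from 1738 CPM in heart 4 to 5432 in heart 1, and miR-144-3p (31.9%) from 237 in heart 6 to 556 in heart 2. The leukocyte miR-142a-3p (33.6%) ranged from 57.5 to 143.4 CPM and miR-208b-3p (31.8%) from 68.8 in heart 6 to 181.5 in heart 5.

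**Figure D3:**
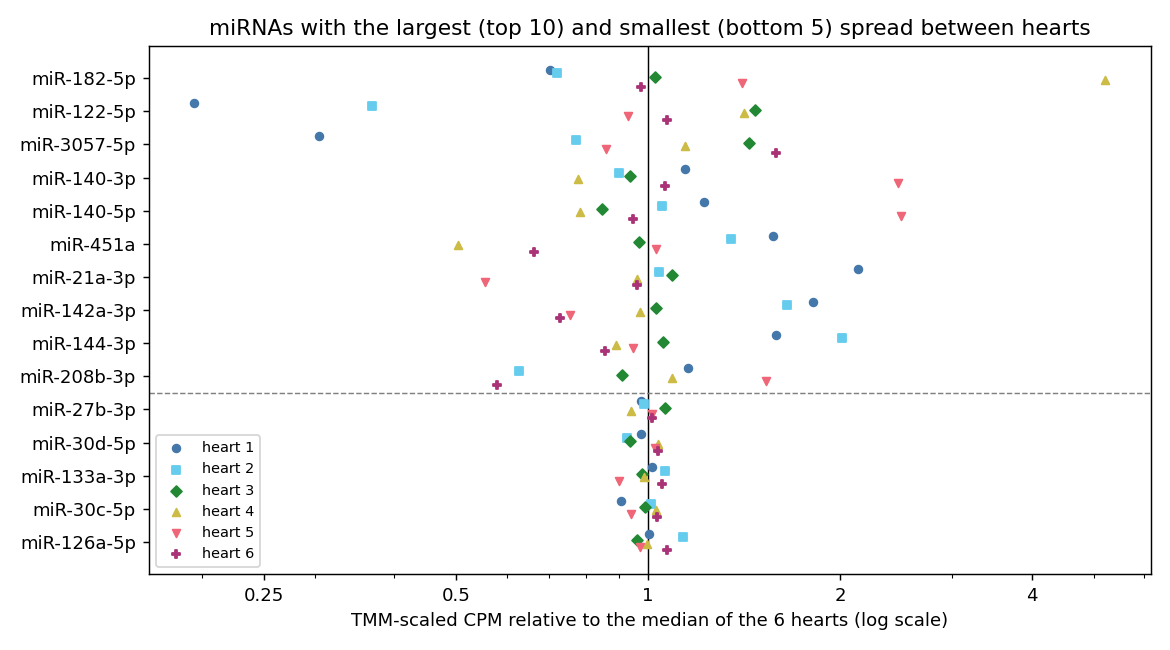
TMM-scaled CPM relative to the median of the 6 hearts (horizontal log axis) for the 10 most variable miRNAs by BCV, above the dashed line, and the 5 least variable by BCV, below it, with a point for each heart. Heart 4 stood apart in miR-182-5p (190 CPM) and heart 5 in miR-140-3p (1735 CPM).

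miRNAs of one genomic cluster varied together between hearts. Over 51 pairs of 50 miRNAs in 16 clusters the median r was 0.66, against a median of 0.03 with permuted membership, and p = 1e-05 was the smallest that 100000 permutations can give (permutation test, one-sided). The imprinted miR-127 cluster had a median r of 0.93, the erythroid pair of miR-144 and miR-451a hairpins 0.90, the miR-106b cluster in Mcm7 0.83 and the miR-379 cluster 0.81. miR-23a and miR-27a had an r of 0.73, and miR-199a-5p with miR-214 a median of 0.68. The miR-143 and miR-145a hairpins (0.15), the miR-322 cluster (-0.01) and miR-23b with miR-27b (-0.20) were the lowest. The result leaned on heart 5, without which the median r was 0.38 (permutation p = 0.0015), and without hearts 4 and 5 it was 0.29 (permutation p = 0.033, n = 4). miRNAs are not independent replicates.

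**Figure D4:**
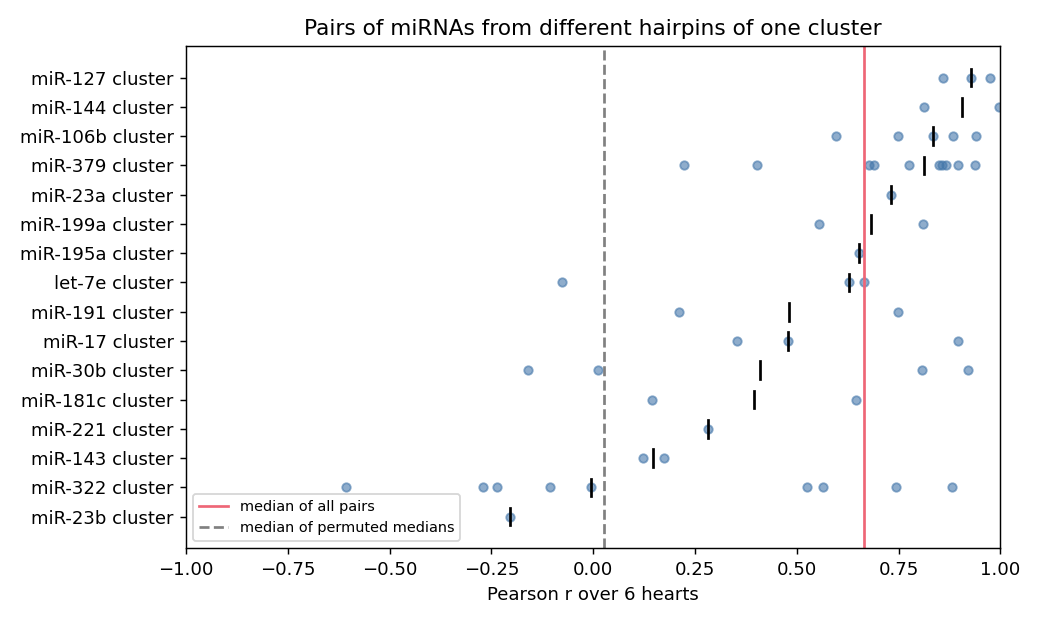
Pearson r over 6 hearts (horizontal axis) for each pair of miRNAs from different hairpins of a cluster (points), with black lines for the cluster medians, the red line for the median of all 51 pairs and the dashed line for the permuted median. The miR-127 cluster lies highest at a median of 0.93 and the miR-23b cluster lowest at -0.20.

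The cell-type lists gave no pair that varied together after adjustment. Of 15 pairs, 0 passed an adjusted p of 0.05 and 2 had an unadjusted p under 0.05 (exact permutation test, two-sided, n = 6). Cardiac and skeletal muscle with endothelial miRNAs had r = 0.87 (exact p = 0.0236, adjusted p = 0.198) and rho = 0.89 (exact p = 0.0333), and r = 0.88 without hearts 2 and 5. Since miR-133a-3p made up 89.5% of the muscle list and miR-126a-5p 86.2% of the endothelial list, this r mostly reflects those miRNAs. Cardiac and skeletal muscle with leukocyte miRNAs had r = 0.85 (exact p = 0.0264, adjusted p = 0.198) and rho = 0.83 (exact p = 0.0583), and r = 0.38 without hearts 2 and 5, the farthest from the median of the muscle list after TMM scaling. It rests on those, and the 4 that remain are too few to decide. The smallest exact p possible with 6 hearts is 0.00278, so after adjustment over 15 pairs a single pair could pass only close to that value. Recovery of related lists was not simulated, so the lack of calls does not show that the lists vary independently.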

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

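The tests of explanations in this part were chosen after the results were seen. Folds are plain ratios of scaled counts, and log2 excesses of single miRNAs over the median of the other hearts add a prior count of 1, both after TMM scaling unless another is named. In 95 series of 6 values, 12 had 1 heart far from the other 5 by Dixon's criterion, where chance flags about 1 in 20 unrelated series. The series are related to each other, and 5 were picked for their spread, of which 4 were among the 12, so the number is not a test. Heart 5 accounted for 6, heart 4 for 5 and heart 1 for 1.

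Heart 4 stood apart in miR-375-3p at 23.4 CPM (others 0.420 to 2.16), miR-183-5p at 66.8 CPM (5.88 to 16.5), miR-182-5p at 208.3 CPM (24.8 to 53.3), miR-222-3p at 121.8 CPM (80.5 to 90.7) and miR-194-5p at 197 CPM (161 to 174), though miR-194-5p did not stand apart after TMM scaling (1.04-fold the median of the others) or with DESeq2 size factors (1.08-fold). The first 3 were 16.2-fold, 7.24-fold and 5.34-fold the median of the other hearts after TMM scaling. Library scaling could not produce this, since their median log2 excess was at least 2.83 under TMM, DESeq2 size factors and library totals. A candidate explanation, as a hypothesis, is RNA of the pancreas in this library, since heart 4 held 85.2% of the 27 reads of the exocrine pancreas miRNAs miR-216a-5p, miR-216b-5p and miR-217-5p (exact binomial 95% interval 66.3% to 95.8%), against 13.4% of all counts. They reached 5.80 CPM together, and the neural miR-124-3p, with 19 of 25 reads in heart 4, is not accounted for. Epithelial cells cannot be told apart from this, since miR-200b-3p (1.88-fold), miR-200c-3p (1.53-fold) and miR-429-3p (2.35-fold) were above the median of the others and miR-200a-3p (0.955-fold), miR-141-3p (0.931-fold) and miR-203-3p (0.861-fold) below, with a median log2 excess of 0.73 (SD 0.54) over the 4 with under 10 CPM in the other hearts. Whether such RNA came with the tissue or from another library stays open, and no explanation within the heart's own cells was tested.

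Heart 5 stood apart in the Dlk1-Dio3 locus at 0.305% of counts (others 0.168% to 0.202%), miR-140-3p at 1808 CPM (600 to 779) and miR-140-5p at 275 CPM (89.0 to 125.4). The same held for miR-199a-3p at 4900 CPM (2563 to 3070), miR-199b-3p at 259 CPM (132.5 to 166.1) and miR-200a-3p at 13.3 CPM (3.55 to 6.72), where miR-199a-3p and miR-199b-3p have the same sequence and count as 1 measurement. Of the 23 Dlk1-Dio3 members with a mean of at least 10 reads 23 were above the median of the other hearts, with a median log2 excess of at least 0.64 under the 3 scalings, which argues against scaling. GC content is argued against as well, since 66 miRNAs of other loci matched on GC had a median log2 excess of -0.0472 (SE 0.0396). A larger share of fibroblast and mesenchymal cells stays open, with values that go both ways. That list had a median log2 excess of 0.40 with both miR-199 3p names summed without a prior count, but its share of counts was 2.35% in heart 5 against 2.54% in heart 1 and 2.40% in heart 4. The smooth muscle list was raised too (0.21, 4 of 4 members above the median of the others), while the erythroid, endothelial and leukocyte lists had -0.01, -0.10 and -0.30. The heart expresses all 7 list members, and miR-10b-5p, the most abundant, was 0.959-fold, so other sources stay open.

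Heart 1 stood apart in miR-21a-3p at 73.3 CPM (others 20.5 to 38.3).

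Among the 38 antisense entries with no hairpin annotated on their strand, 2 had a mean above the limit of 3 counts. These were an entry antisense to the miR-122 3p arm, with a mean count of 9.17 (6 to 13 reads per library), and one antisense to the miR-335 5p arm, with a mean count of 4.67 (3 to 7).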

How the results depend on the processing

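No paired analysis was possible because the samples form 1 group, with no numbers to pair across groups. Arms and preset pairs were compared within each library. Clusters from coordinates, clusters without the Dlk1-Dio3 locus, and the results without hearts 4 and 5 were chosen after the data were examined. Of 1138 alternative values, 1125 kept their direction and side of the threshold or moved by less than the spread or count limit. Of the others, the number of miRNAs detected was 594 at a mean of at least 1 read and 207 at a mean of at least 100 reads, against 346, by construction of the minimum. The share of the top 10 was 81.4% with families summed, against 73.4%, by construction since more miRNAs enter each sum, and 73.2% to 73.7% with a heart left out. The 14 list shares moved by less than 1 SD under TMM, DESeq2 size factors and each left-out heart. Each arm call was kept with DESeq2 and with no filter, 187 were kept with limma and 139 at a mean of at least 100 reads, where the other 49 were not tested, and 0 turned to the other arm. The preset pairs gave 16 calls with a heart left out, and miR-23a-3p over miR-23b-3p was also called with DESeq2 (log2 ratio 0.12), where the cause was not tested. The common BCV ran from 17.2% at a mean of at least 100 reads to 19.7% with library totals, and from 17.4% to 20.4% with a heart left out, when 210 to 246 miRNAs varied beyond counting noise. Without hearts 4 and 5 it was 14.9%. With no filter 253 of 975 did, and 722 did not against 104, since most added miRNAs have few reads. The BCV of 6 named miRNAs moved over 1.5 times with 1 heart left out, and these are given with the spread. Cluster co-variation passed its permutation test in all 13 alternatives. Its median r was 0.67 with DESeq2 size factors, 0.68 with library totals, 0.44 at a mean of at least 10 reads, 0.54 with Spearman, 0.68 with clusters from coordinates, 0.58 without the Dlk1-Dio3 clusters and 0.38 to 0.74 with a heart left out, lowest without heart 5. List co-variation gave 0 adjusted calls under each alternative and 0 to 3 unadjusted ones. With 5 hearts the smallest exact p is 0.0167, so little could pass. Depth limits the minor arms with a few reads and the list members under 10 reads, for which counting intervals are given.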

Other observations

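The tests in this part were chosen after the results were seen. Some clusters known from other tissues held few of the counts. The large cluster in an intron of Sfmbt2 on chromosome 2, between 10466954 and 10515890, had 64 entries and 18.4 ± 1.97 CPM in all (SD, n = 6), with miR-467d-5p on top at a mean of 13.3 reads. The X-linked cluster between 66776794 and 66839121, near Fmr1, had 20 entries and 7.19 ± 4.09 CPM, with miR-871-3p on top at a mean of 16.7 reads. These clusters and the miRNAs named for them were chosen after their values were seen. The treatment of reads that match several loci is not given, so few counts here need not mean low levels.

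Some mature miRNAs come from 2 loci that share their first 18 bases, or of which one mature sequence contains the other, and their reads were booked on the copies in unequal shares. The copy of miR-133a-3p on chromosome 2 took 84.6% ± 0.751 of its reads, the miR-16-2 copy 92.9% ± 0.230 of miR-16-5p, the miR-26a-2 copy 77.7% ± 0.565 of miR-26a-5p and the miR-1a-1 copy 73.5% ± 0.864 of miR-1a-3p (SD, n = 6). Others were closer to even or varied more, such as miR-181a-5p with 54.7% ± 2.08 on 1 copy and miR-218-5p with 71.5% ± 6.35. The sources used here do not say how reads matching both copies were divided, so these shares are not levels of the loci. In all, 25 miRNAs met this rule and held 19.5% ± 1.04 of the counts. The rule leaves out copies whose annotated sequences overlap but are offset, so more of the counts lie on copies than this. Among them is miR-486-5p, with 14.2% of the counts and 53.7% ± 2.46 of its reads on 1 strand's hairpin. Another is miR-24-3p, with 64.5% ± 1.56 on 1 copy. Whether a read of miR-486-5p could be counted on both strands is not given either.

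miR-1a-3p had few reads next to miR-133a-3p although both come from the same loci. Loss of reads that match both loci is argued against as the whole cause, since miR-133a-3p has the same sequence at both and held 8.90% of the counts. Reads booked on other entries of the miR-1 hairpins are argued against too, since all 6 entries there, antisense ones included, came to 8.55% ± 1.29 of the miR-133a-3p count. A lower ligation yield of miR-1a-3p, a loss specific to its reads in the alignment, and a difference in the tissue stay open, and none of them was tested.

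One hypothesis was that miR-486-5p varies between hearts with red cell content. It correlated with the erythroid miR-451a with r = 0.81 (exact permutation p = 0.0667, adjusted p = 0.133 over 2 relations, n = 6) and rho = 0.77 (exact permutation p = 0.103), and r was 0.45 without hearts 1 and 4. The relation missed the threshold and rests partly on those hearts, so it may or may not hold. miR-451a ranged 3.13-fold between hearts and miR-486-5p 1.65-fold.

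Another hypothesis was that miR-208b-3p from Myh7 varies opposite to miR-208a-3p from Myh6. The correlation was r = -0.58 (exact permutation p = 0.232, adjusted p = 0.232 over 2 relations, n = 6) with rho = -0.26 (exact permutation p = 0.658), and r was 0.80 without hearts 2 and 5. The negative sign rests on hearts 2 and 5, the extremes of miR-208a-3p, and the 4 others are too few to decide, so the relation stays open.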
